A study of Mus musculus and Drosophila melanogaster with 12 samples.

How the data were processed

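Total RNA sequencing was measured in 12 libraries: 4 from hindguts of 4-day fly pupae and 8 from livers of mouse embryos at E11.5 and E13.5. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into libraries with a stranded total RNA kit. Per the submitters' processing notes, the genome builds were dm6 and mm10. The aligner, the counting program, the treatment of reads that match several copies of an element and the scaling for library depth are not given in the sources used here.

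The values came in 3 tables of transposable elements, 1 for the fly hindgut and 1 for each mouse stage. Each table had 2 columns of values, and per the labels each column combined 2 replicates. The fly values are a signal of element abundance deposited by the authors with no unit in the header. The mouse values are named effective counts in the deposited headers, are not whole numbers and were treated as values of unknown scale. Among values of at least 1 with 7 digits, 114 of 123 in the fly table, 186 of 199 in the E11.5 table and 178 of 194 in the E13.5 table ended in 5. Means of 2 numbers of 6 digits have such endings. The values per library were not analysed here, so no test, standard deviation or p-value could be computed, and differences are described as those between the authors' combined values. The depth of the libraries is unknown, so no interval or detection limit is given. A planned count test and a planned linear model, both of which need values per library, were not run.

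The fly columns were assigned by their names to the white hairpin control and the crm hairpin. The 4 mouse columns carry the suffixes x and y in their headers, which name no genotype. They were assigned to no genotype, because only the order of the columns would have given one. Mouse ratios are therefore y over x and say nothing about the direction of the effect of the mutation. Whether a suffix stands for the same genotype in both tables is likewise not stated in the sources used here. The titles call the mouse controls WT and the characteristics call them Cramp1 heterozygotes.

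For each element the log2 ratio of (value + 1) between the 2 columns was computed, so ratios of low elements are understated. Elements with a mean of at least 1 over both columns were kept. In the tables of both mouse stages, 6 rows that repeat a name under a second spelling were left out of the 1069 rows. Of the rest, 742 at E11.5 and 741 at E13.5 were at 0 in both columns. Families with names late in the alphabet, such as RLTR, RMER and ORR1, were not analysed here. The mouse tables also hold 217 rows named after chromosome bands, in the manner of piRNA-producing loci, and rows of rat and other species' repeats. Reads of near-identical families can match several rows, so values of single B2, LINE-1 and IAP rows are uncertain.

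Element lists were fixed by name before the data were examined, and the classes in the mouse row names were added as lists. In mouse the B2 list and class SINE2-tRNA hold the same rows above the minimum, so they are not separate evidence. Other fixed lists share rows with the classes, and all MaLR rows are in class ERV3. In mouse a row counted in the first fixed list it matched. The name LTRIS stood in the patterns of both the other ERVK and the ERV1 lists, so its rows counted as other ERVK, although most are classed as ERV1 in the row names. The row MMETN matched no list. The median log2 ratio of each list with at least 3 elements was placed among 10000 random lists of the same size, drawn within 5 bins of mean level. Percentiles under 2.5 or over 97.5 are called outside the central 95%. They describe these columns and are not p-values. The procedure was tested on simulated ratios at the levels of the fly elements. Of 1000 simulated lists of 20 elements with no shift, 63 fell outside the central 95%, of 1000 with a log2 shift of 1, 765 did, and of 1000 with a shift of 2, 1000 did. With 5 elements the numbers were 57, 307 and 831. The simulated ratios were independent normal draws unrelated to level, so these numbers need not hold for the measured ratios. Levels of the mouse elements were not simulated. Elements named in the text are the 10 highest and 10 lowest ratios among elements at or above the median level, a fixed list of well-known elements, and the 3 most abundant members of each list. Fly elements whose names are numbers are counted in their lists and not named one by one. Mouse elements on the fixed list were matched to the spelling of the rows after these had been seen. The summed share of LTR elements was also chosen as a summary after the tables had been seen.

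Alternatives were a pseudocount of 0.1 or 10, no filter, a minimum mean of 10, centring of the log2 ratios on their median and, for shares, leaving out the most abundant element. Scaling both columns to the same total, leaving out the rows named after piRNA loci, leaving out 1 B2 row, adding MMETN to the ETn/MusD list and leaving the LTRIS rows out of the other ERVK list were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.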

Results

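Transposable element RNA was measured by total RNA sequencing in 6 groups of 2 libraries. In the fly, hindguts of 4-day pupae carried a hairpin against crm, also called dCramp1 in the labels, or a hairpin against white, an eye pigment gene, as the control. In the mouse, livers of Cramp1 mutant embryos and of control embryos were taken at E11.5 and E13.5. The series asks how a gene conserved between fly and mouse restrains mobile elements. The tables analysed here give 1 value per element and column, combined by the authors from 2 libraries, so the spread between replicates is unknown and no difference below was tested. The knockdown itself could not be checked, because the tables analysed here hold elements and not host genes.

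Most elements had a higher signal in the crm knockdown than in the white control of the fly hindgut. Of the elements with a mean of at least 1, 71 were at least 2-fold higher, 2 were at least 2-fold lower and 42 lay between. The median log2 ratio was 1.42, a 2.68-fold difference, and 10 elements lay below 0. The summed signal was 21225 in the control and 48918 in the knockdown. The 10 highest ratios among elements at or above the median level included the LTR retrotransposons accord and GATE and the telomeric retrotransposons TAHRE and HeT-A. GATE, which is in none of the lists, had 20.1 in the control and 1315 in the knockdown. Because the scaling of the columns is unknown, this general difference cannot be separated from one of depth, and ratios are also given relative to the median element. After centring on the median, 27 elements were at least 2-fold higher and 18 at least 2-fold lower, and with equal column totals 38 were higher and 12 lower.

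**Figure D1:**
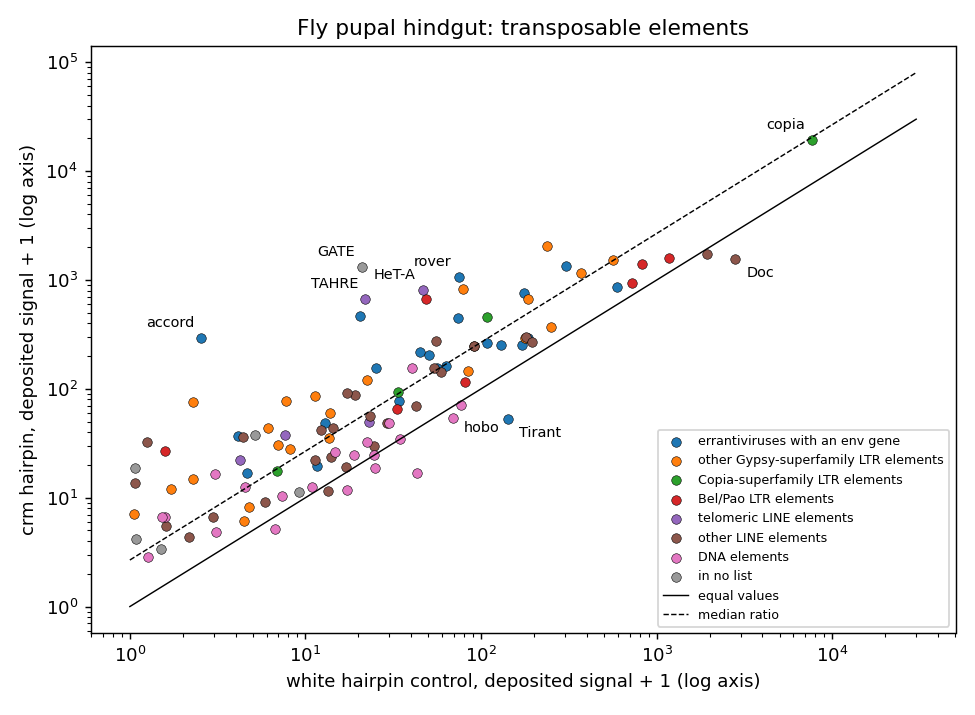
Deposited signal plus 1 of the transposable elements with a mean of at least 1 in the white hairpin control (x axis, log) and the crm hairpin (y axis, log) of the fly pupal hindgut, each point the authors' combined value of 2 libraries, coloured by element list. The solid line marks equal values and the dashed line the median log2 ratio of 1.42, and 10 points lie below the solid line.

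Errantiviruses, the gypsy-like LTR elements of which several carry an envelope gene, had a median log2 ratio of 1.89, which is 0.47 above the median element. Of 22 members, 16 were at least 2-fold higher, 1 was at least 2-fold lower and 5 lay between, and after centring 6 were at least 2-fold higher and 1 lower. The signal of accord was 1.55 in the control and 292 in the knockdown, that of gypsy5 was 19.4 and 461, and that of rover was 73.8 and 1061. ZAM had 3.11 and 36.1, and Idefix had 43.8 and 218. These elements lay above the median element too, by 5.42 for accord, 1.76 for ZAM and 0.87 for Idefix. The ratios of accord and ZAM depend on the pseudocount, since their control values are low: with 10 in place of 1 the log2 ratio was 4.71 in place of 6.84 for accord and 1.82 in place of 3.18 for ZAM. The endogenous retrovirus gypsy had 108 in the control and 263 in the knockdown, a log2 ratio of 1.28 that is 0.14 below the median element. Tabor, the most abundant member in the knockdown, had 302 and 1342. HMS-Beagle, with 590 and 857, was 0.88 below the median element. Tirant had 142 in the control and 52.2 in the knockdown, a log2 ratio of -1.42. Both rescalings lower every fly ratio, so Tirant stays below 0 under them by construction. The list's median stood at the 96.2nd percentile of random lists and reached the 98.0th with a pseudocount of 0.1.

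The other Gypsy-superfamily elements had a median log2 ratio of 2.10, which is 0.68 above the median element and becomes 1.36 with a pseudocount of 10. As deposited, 18 of 23 members were at least 2-fold higher and none lower, and after centring 10 were at least 2-fold higher and none lower. The signal of mdg1 was 237 in the control and 2042 in the knockdown, that of gypsy4 was 78.0 and 817, and that of Circe was 6.71 and 77.0. The log2 ratio of blood was 1.65 and that of flea 1.44, close to the median element, while mdg3, at 0.58, lay 0.84 below it. The percentile of this list was 96.2. The 4 Copia-superfamily elements were each at least 2-fold higher as deposited, with a median of 1.40 that becomes -0.0159 after centring, when none was. The most abundant element of the table, copia, had 7637 and 19414, a log2 ratio of 1.35 that becomes -0.0745 after centring. Of the 7 Bel/Pao elements, 2 were at least 2-fold higher, and after centring 2 were higher and 1 lower. Max-element had 47.3 in the control and 674 in the knockdown. The abundant members roo, diver and 3S18 had log2 ratios of 0.44, 0.38 and 0.77, each below the median element, and rooA had 0.52.

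All 5 telomeric LINE rows, of elements that maintain chromosome ends in flies, were at least 2-fold higher as deposited, and 2 were after centring. HeT-A had 45.8 in the control and 809 in the knockdown, and TAHRE had 20.9 and 672. TART-A and TART-C had log2 ratios of 2.40 and 2.30, or 1.25 and 1.49 with a pseudocount of 10. TART-B had 1.13, which lies 0.30 below the median element. The summed signal of the list was 98.5 in the control and 1589 in the knockdown, and its share of all element signal was 0.464% and 3.25%. Its median stood at the 83.9th percentile, inside the central 95% of random lists of 5. In simulations of independent normal ratios at this list size, a log2 shift of 1 placed 307 of 1000 lists outside. These rates need not hold for the measured ratios.

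The other LINE elements had a median log2 ratio of 1.18, or 0.24 below the median element, with 15 of 27 at least 2-fold higher and none at least 2-fold lower as deposited. After centring the balance was the other way, with 3 at least 2-fold higher and 5 at least 2-fold lower. R1A1-element, which inserts into ribosomal RNA genes, had 16.3 in the control and 90.0 in the knockdown, and R2-element, which does so too, had 179 and 299. Relative to the median element, R1A1-element was 0.97 above and R2-element 0.68 below. I-element had 52.9 and 155, the latter a value it shares with 1 DNA element to the last digit, and jockey had 193 and 270, or 0.94 below the median element. The most abundant members went the other way: Doc had 2802 in the control and 1557 in the knockdown, and F-element had 1941 and 1715. The list's summed signal was 5610 in the control and 5290 in the knockdown. Its share of all element signal was 26.4% and 10.8%. As deposited, the list's sum differed little and the sum over all elements was higher in the knockdown. Because the scaling of the columns is unknown, a fall of this list cannot be told apart from a rise of the other elements. The list's median lay inside the central 95% of random lists, which spanned 0.77 to 1.95.

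DNA elements had the lowest median of the 7 lists, 0.47 as deposited and 0.95 below the median element. Of 21 members, 6 were at least 2-fold higher, 1 was at least 2-fold lower and 14 lay between as deposited, while after centring 1 was at least 2-fold higher and 10 were at least 2-fold lower. The median stood at the 0.01st percentile of random lists of the same size and level, and this was the only fly list outside the central 95%. The signal of hobo was 68.3 in the control and 53.5 in the knockdown, that of Tc1-2 was 75.5 and 69.7, and that of pogo was 21.3 and 31.3. P-element had 9.91 and 11.4. NOF, named after its value was seen, had 42.4 and 15.8 and was with Tirant the other element at least 2-fold lower. The 4 LTR lists together, which leave out GATE, made up 70.9% of the element signal in the control and 81.9% in the knockdown, and copia alone made up 36.0% and 39.7%. Shares also depend on the other rows. The LINE element Doc made up 13.2% in the control and 3.18% in the knockdown, and F-element 9.15% and 3.51%. The LTR share without these LINE rows was not computed, so a gain of LTR elements as a class is not shown. The share of the Bel/Pao list was lower in the knockdown.

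**Figure D2:**
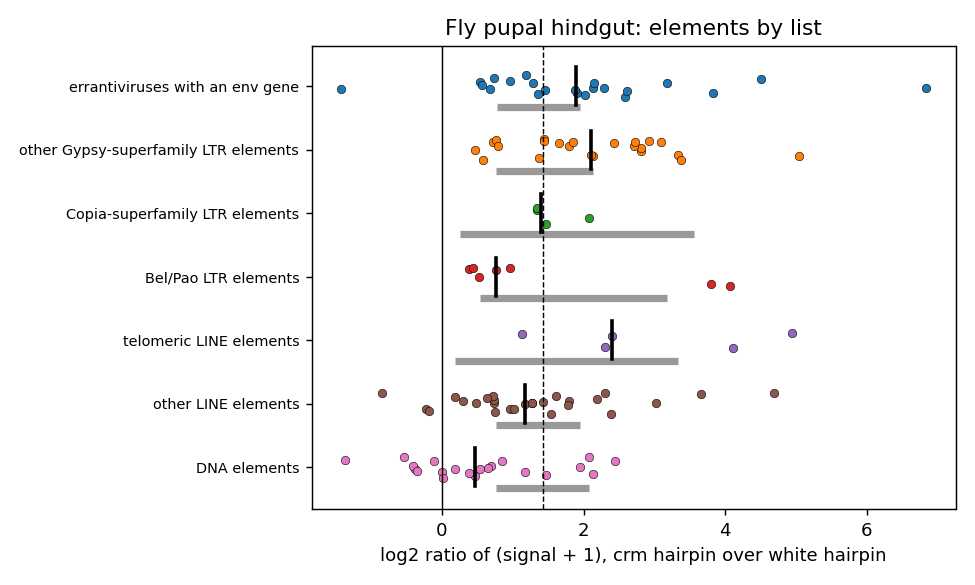
Log2 ratio of (signal + 1), crm hairpin over white hairpin (x axis), of the members of 7 element lists in the fly hindgut, each point 1 element and each black bar the median of a list. The grey bar under each list spans the central 95% of medians of 10000 random lists, the solid line marks 0, and the dashed line marks the median element at 1.42. The DNA elements, with a median of 0.47, lie left of their grey bar.

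In the mouse the comparison is of the Cramp1 mutant with the control liver at each stage, but the genotype of the 2 columns is not given, so values are stated as column x and column y. At E11.5 the 2 columns were close: of 191 elements with a mean of at least 1, 9 were at least 2-fold higher in y, 4 were at least 2-fold lower in y and 178 lay between. The median log2 ratio was 0.21, and the column sums were 19674 in x and 24101 in y. After centring, 5 elements were at least 2-fold higher in y and 4 lower. Elements of the LTR classes stood at both ends of the ratios among elements at or above the median level, with MERVL, MTAI and ERVB4_1B-I among the 10 lowest and the following among the 10 highest. MMERGLN_I, the internal part of a retrovirus of class ERV1, had 671 in x and 1388 in y, and its LTR, MMERGLN_LTR, had 61.9 and 125. ETnERV3, an early transposon relative, had 11.3 and 27.3, MMETN had 1578 and 2434, and the intracisternal A particle element IAPEY4_I had a log2 ratio of 0.68.

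The 6 rows that the fixed name pattern of the ETn/MusD list took from the E11.5 table had a median log2 ratio of 0.47, 0.25 above the median element and at the 97.9th percentile of random lists. The pattern did not take MMETN, with which the list of 7 had a median of 0.51 at the 99.6th percentile. ERVB7_1-I, the most abundant of the 6, had 608 in x and 805 in y. Of 39 rows of class ERV2, 3 were at least 2-fold higher in y, or 1 after centring, and the class stood at the 98.1st percentile, but inside the central 95% with a pseudocount of 10, with equal totals and without the rows named after piRNA loci. The 20 IAP rows stood at the 78.4th percentile, with IAPEZI at 479 and 591. IAPLTR1_Mm, IAPLTR1a_MM and IAPEY3_I had log2 ratios of 0.19, 0.40 and 0.03, and ETNERV and ETnERV2 had 0.51 and 0.42. The list of 22 other ERVK rows, with MMERVK10C at a log2 ratio of 0.43, stood at the 61.8th. It holds 7 LTRIS rows, whose row names do not class them as ERVK, and the other 15 stood at the 87.6th. The elements of class ERV3, which holds MERVL and the MT families, stood at the 1.05th percentile: MERVL had 657 and 654, and MTAI had 249 and 247. The MERVL and MT2 list alone stood at the 15.7th, and the MaLR list at the 2.245th, or the 2.525th with no filter. The list named young LINE-1 was taken by name pattern, so it does not separate LINE-1 families by age. All 30 of its rows were higher in y as deposited and 23 lay above the median element. Their median of 0.26 becomes -0.0354 with equal totals. The list stood at the 96.3rd percentile, or the 98.8th with a minimum mean of 10. L1MdTf_I had 349 and 475, and L1MdA_I and L1MdGf_I had log2 ratios of 0.29 and 0.46. The 3 rows of the list named older LINE-1, also taken by name, stood at the 57.7th, and all rows of class L1 at the 95.2nd. The 3 ERV1 rows stood at the 81.9th, and class ERV1 at the 89.9th, or the 99.6th with a minimum mean of 10. That minimum kept only LTRIS2, MMERGLN_I and MMERGLN_LTR of class ERV1. The 3 satellite rows were low, with the major satellite GSAT_MM at 3.25 and 10.7, and stood at the 98.2nd percentile, but inside the central 95% with a pseudocount of 10 or no filter.

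A single B2 row had the highest ratio of the E11.5 table, with 5.45 in x and 82.4 in y, while the closely related row B2_Mm2 had 22.7 and 26.5. All B2 rows together had 109.9 in x and 203 in y, so the sum differed too. The 8 B2 rows as a list stood at the 84.3rd percentile. The 72 rows named after piRNA loci had a median of 0.14, at the 0.09th percentile, or the 6.45th with a pseudocount of 10. The most abundant of these had 2507 in x and 2799 in y. The 4 elements at least 2-fold lower in y all had means under 5, and 3 of these were rows named after piRNA loci. LTR elements held 30.8% of the signal of all rows analysed in x and 34.8% in y, and 53.4% and 56.6% without the rows named after piRNA loci. Class ERV1, which holds MMERGLN_I, held 3.92% in x and 6.48% in y, class ERV2 6.77% and 7.22%, and class ERV3 7.86% and 6.54%. The LTR share without MMERGLN_I or MMETN was not computed, so a difference across LTR elements in general is not shown.

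At E13.5, of 192 elements, 10 were at least 2-fold higher in y, 1 was at least 2-fold lower and 181 lay between, with a median log2 ratio of 0.34. After centring, 4 were at least 2-fold higher and 7 lower. Of the 10 highest ratios among elements at or above the median level, 5 belonged to elements that were also among the 10 highest at E11.5: IAPEY4_I, MMERGLN_I, MMERGLN_LTR, ETnERV3 and a row named after a piRNA locus. IAPEY4_I had 120 in x and 290 in y, MMERGLN_I had 732 and 1408, and ETnERV3 had 9.59 and 19.7. The retrotransposon MMVL30 had a log2 ratio of 0.88, and L1MdTf_II had 240 and 400. IMPB_01, a satellite, had 2.42 and 6.66. Among elements at or above the median level, the lowest ratios belonged to B2_Rn2, with 23.8 and 11.7, and ERVB4_1B-I, with 34.1 and 22.5. The element at least 2-fold lower in y was a row named after a piRNA locus, with 2.20 and 0.383. The column sums were 17456 in x and 22917 in y, and the LTR share of all rows analysed was 30.9% and 33.1%, or 48.2% and 50.6% without the rows named after piRNA loci. Class ERV1 held 4.78% in x and 6.88% in y, class ERV2 6.51% and 6.93%, and class ERV3 7.31% and 6.04%. Here too the LTR share without MMERGLN_I or MMETN was not computed.

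Of 16 lists in the E13.5 table, 15 of them with different members, 2 lay outside the central 95%. These were class ERV3, at the 0.11th percentile with a median of -0.01, and the MaLR elements, at the 1.75th with a median of 0.13, though the MaLR list lay inside with a pseudocount of 10, no filter or a mean of at least 10. All MaLR rows also belong to class ERV3, so these 2 lists are not separate evidence. Class ERV2 lay outside with a pseudocount of 10, at the 98.4th. In E11.5 liver the MaLR median was 0.05, and 6 of 16 lists lay outside. Among these, the MaLR list lies within class ERV3, and the ETn/MusD list shares rows with class ERV2. Without the rows named after piRNA loci, 5 lists lay outside at E13.5: the B2 list and class SINE2-tRNA, which hold the same 9 rows and stood at the 1.45th, and the satellites, at the 98.4th, came in addition. MERVL had 551 in x and 585 in y, and the MERVL and MT2 list stood at the 2.91st percentile. MTA_Mm had 338 and 385. The 20 IAP rows stood at the 71.7th percentile, the 6 ETn/MusD rows at the 75.9th, or the 88.2nd with MMETN, and class ERV2 at the 87.1st. The list of 20 other ERVK rows stood at the 71.2nd, and without its 6 LTRIS rows at the 94.8th. IAPLTR1_Mm, IAPLTR1a_MM and IAPEY3_I had log2 ratios of 0.37, 0.65 and 0.59, ETNERV and ETnERV2 had 0.36 and 0.21, and L1MdA_I and L1MdGf_I had 0.39 and 0.50. The 30 rows of the list named young LINE-1 were all higher in y as deposited, and 17 lay above the median element. Their median of 0.36 becomes -0.0208 with equal totals. This list stood at the 67.7th percentile, the 3 rows of the list named older LINE-1 at the 36.4th and class L1 at the 64.3rd. The 9 B2 rows stood at the 5.47th, the 3 satellites at the 96.2nd, the 3 ERV1 rows at the 26.7th, class ERV1 at the 30.7th and the 73 rows named after piRNA loci at the 27.1st. The B1, the B4, ID and MIR, and the DNA transposon lists had at most 1 element above the minimum at either stage.

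Across 186 elements measured at both stages, the log2 ratios of the 2 tables had a Pearson r of 0.01 and a Spearman rho of 0.17. These are correlations across elements, which are not independent replicates, and whether y stands for the same genotype in both tables is not given. Of these elements, 135 were higher in y at both stages, where 129 would be from the numbers at each stage alone, since y was higher for most elements in both tables. The number lower at both was 11, where 5.12 would be, which is the same excess and not separate evidence. After centring each stage on its median, 53 were above it at both stages and 53 below it at both, where 46.5 would be in each case. These counts are equal by construction. Over the 100 elements with a mean of at least 10, r was 0.31 and rho 0.57. Leaving out 1 B2 row gave an r of 0.0255 over the elements with a mean of at least 1, and an r of 0.67 and a rho of 0.59 over those with a mean of at least 10. MMERGLN_I had 1.05 and 0.94, MMERGLN_LTR 1.01 and 0.91, ETnERV3 1.21 and 0.97, and IAPEY4_I 0.68 and 1.27, at E11.5 and E13.5. ERVB2_1A-I, named after its values were seen, was the 1 element at least 2-fold higher in y at both stages, with log2 ratios of 1.57 and 1.44 at values under 10. No interaction was tested, so no difference between the stages is shown.

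**Figure D3:**
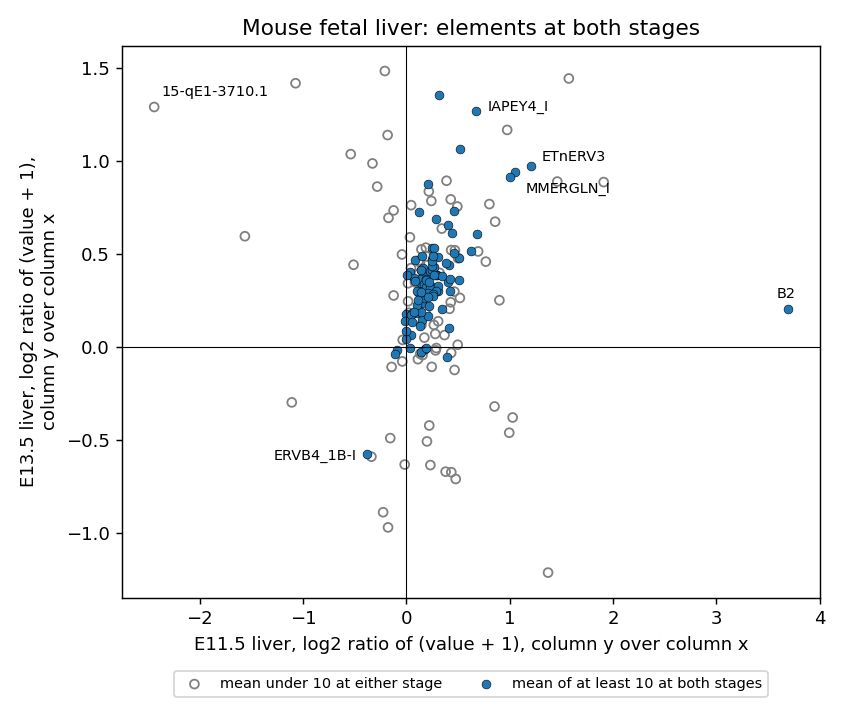
Log2 ratio of (value + 1), column y over column x, of 186 elements in mouse fetal liver at E11.5 (x axis) and E13.5 (y axis), each point 1 element and each value the authors' combination of 2 libraries. Filled points are the 100 elements with a mean of at least 10 at both stages, among which MMERGLN_I lies at 1.05 and 0.94 and 1 B2 row lies apart at 3.69 and 0.20.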

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

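Scaling to equal totals, leaving out the rows named after piRNA loci, the B2 row or the LTRIS rows, and adding MMETN were chosen after seeing the data, and the cause of the changes below was not tested. No paired analysis was possible because each column already combines 2 replicates. For the same reason leaving out replicates, other count normalizations and a linear model without a trend could not be run. With no replicates, a log2 ratio counts as moved when it shifts by over 0.58 (1.5-fold).

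In the fly, centring gave 27 elements higher and 18 lower in place of 71 and 2, and equal totals gave 38 and 12. Among elements named and list medians at least 2-fold apart as deposited, centring reversed the sign for gypsy (-0.14), copia (-0.0745), TART-B (-0.30) and 1 further errantivirus (-0.0615), and for the Copia-superfamily (-0.0159) and other LINE medians (-0.24). Equal totals reversed TART-B (-0.0432). Of those less than 2-fold apart as deposited, 12 named elements turned negative with centring and 12 with equal totals, among them roo (-0.98 and -0.76), diver (-1.04 and -0.82) and jockey (-0.94 and -0.72), as did the Bel/Pao (-0.65 and -0.44) and DNA medians (-0.95 and -0.70). Fly lists outside the central 95% numbered 2 with a pseudocount of 0.1, and the DNA list stayed outside under every alternative. Centring shifts all ratios alike and cannot change a percentile, and equal totals shift them nearly alike. Only the pseudocounts and the filters could therefore have moved the DNA list. A pseudocount of 10 moved 5 named elements, Circe (2.38) among them, and the other Gypsy-superfamily (1.36) and telomeric medians (1.49), and one of 0.1 gave accord 7.47.

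At E11.5, elements higher in y numbered 15 with a pseudocount of 0.1, 2 with 10, 4 at a mean of at least 10, and 5 with centring and with equal totals. Elements lower numbered 0 with a pseudocount of 10 and at a mean of at least 10, and 1 without the piRNA-locus rows. Lists outside numbered 3 with a pseudocount of 10. At E13.5, elements higher numbered 19 with a pseudocount of 0.1, 1 with 10, 3 at a mean of at least 10, 4 with centring and with equal totals, and 6 without the piRNA-locus rows. Elements lower numbered 4 with a pseudocount of 0.1, 2 with no filter, 7 with centring, 5 with equal totals, and 0 with a pseudocount of 10, at a mean of at least 10 and without the piRNA-locus rows. Lists outside numbered 1 with no filter and at a mean of at least 10, and 5 without the piRNA-locus rows, where the B2 list (1.45), class SINE2-tRNA (1.45, the same rows) and the satellites (98.4) were added. With a pseudocount of 10 the number stayed at 2, but class ERV2 (98.4) was outside and the MaLR list (2.98) was not. At E11.5 a mean of at least 10 placed the list named young LINE-1 (98.8) and class ERV1 (99.6, median 1.01) outside. That minimum kept only LTRIS2, MMERGLN_I and MMERGLN_LTR of class ERV1. A pseudocount of 10 gave 2.58 for the B2 row at E11.5 and satellite medians of 0.37 and 0.26 at E11.5 and E13.5. Centring turned the sign of 15 named elements at each stage, and equal totals that of 20 at E11.5 and 22 at E13.5, all under 2-fold apart as deposited.

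The correlation between stages, 0.01, was -0.12 with a pseudocount of 0.1, 0.37 with 10, 0.31 at a mean of at least 10, 0.17 as Spearman's rho, and 0.67 at a mean of at least 10 without the B2 row. The LTR share was higher in the knockdown without copia and in y without the largest or all piRNA-locus rows. No mouse LTR row was dropped. Adding MMETN or leaving out LTRIS rows moved no list outside or inside. Unknown depth leaves low elements' precision open.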

Other observations

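All tests of explanations in this part were chosen after the values they use had been seen.

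A group of 5 fly elements had a control signal under 1 and a knockdown signal of at least 10, and 0 elements had the opposite. G-element, a LINE, had 0.245 in the control and 31.2 in the knockdown, and Helena, another LINE, had 0.0669 and 12.5. Stalker3 had 0.0661 and 17.8, aurora-element had 0.588 and 25.7, and gypsy3 had 0.714 in the control. These were picked by their values. The limits were applied to the columns as deposited, where the median log2 ratio was 1.42, and the counts were not repeated after rescaling. A one-sided count can therefore follow from the general difference, which cannot be told apart from one of depth.

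In mouse liver, B2 rows were higher in both columns of the E13.5 table than of the E11.5 table. The scaling of the tables against each other is not given. B2_Mm2 had a mean of 24.6 at E11.5 and 265 at E13.5, and B2_Rat2 had 35.2 and 442. B2 rows held 0.559% and 0.844% of the element signal in the E11.5 columns and 7.87% and 6.72% in the E13.5 columns. The single row that stood apart at E11.5 had 5.45 in column x, against 82.4 in y and 75.9 and 87.6 at E13.5.

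The median log2 ratio of the 9 B2 rows, E13.5 over E11.5, was 3.22. One factor between the tables would shift the other elements alike, but the median of the other 188 was -0.16 and their highest 0.71. Reads divided differently among B2 rows would leave their sum unchanged, but the log2 ratio of the sums was 3.22. Better recovery of short transcripts at E13.5 may be a cause and stays open, since B1_Mus1, at 0.62, was the only other short element above the minimum. A difference between the stages was not tested and stays open too.

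In the fly, the DNA list stood at the 0.01st percentile of random lists. A single factor between the columns leaves this percentile nearly as it is, so the percentile tests nothing about such a factor. Larger ratios of low elements could place lists apart. The random lists were already matched on mean level, and the rank correlation of ratio and mean level across elements was 0.0523. The mean level includes the knockdown value, so this correlation cannot exclude a relation of the ratio with the control level. The median log2 ratio of 1.42 over all elements cannot be told apart from a difference in depth, since the depths are not given. An effect of the knockdown that differs between element classes is a hypothesis, and the spread between replicates, which could not be measured, may account for part of the pattern. The groups carried different hairpins, so any other difference between their fly stocks cannot be told apart from the knockdown.

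I-element and 1 abundant DNA element share the same knockdown value, 155, to the last digit, while their control values are 52.9 and 39.3. From the 26 pairs of knockdown values within 1% of each other, 0.00839 identical pairs would be expected by coincidence. A value copied between the rows is a candidate explanation that was not tested, and the ratios of these elements are uncertain.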
